A study of Caenorhabditis elegans with 9 samples.

How the data were processed

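RNA was sequenced from whole wild-type C. elegans of the L4 stage kept for 4 h on plates made with NaCl (100 mM), KCl (100 mM) or the NGM salts, with 3 libraries per condition and 9 in all. Per the labels, libraries were made from total RNA and sequenced as paired-end reads of 150 bp, with about 6 Gb of clean data each. The values are expected counts, as deposited: estimated reads per gene and library, not scaled between libraries, for which the authors name STAR 2.7.1a, RSEM 1.3.3, R 4.3.1 and DESeq2 1.40.2 without giving the role or order of each. The genome build, the annotation and the strandedness are not given in the sources used here.

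The table held 46904 genes, of which 857 had at least 1 count that was not whole (621 of those tested, 4.8%). Of the identifiers, 44017 were matched to a symbol and 46817 were in the Ensembl 115 annotation (WBcel235), from which positions were taken. Mitochondrially encoded genes matched no symbol and give no result. Library totals run from 8592683 to 11181235. The floor for a gene at 0 is 3 counts over the 3 libraries of a condition, and such floors cover counting error only.

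Counts were rounded and tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with limma 3.58.1. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 13060, and libraries were scaled by TMM factors between 0.961 and 1.063. A single model with 1 term per condition was fitted to all 9 libraries. P values are two-sided and were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. NaCl was compared with KCl, with NGM and with the mean of both (3211 genes differed from the mean, 1800 higher and 1411 lower), and KCl with NGM. PD up and PD down are the genes that passed in the same direction against both KCl and NGM. Of 45 gene lists, 44 had at least 3 tested members and were tested with camera (preset correlation 0.01), adjusted over the lists of each comparison, and again with an estimated correlation, with fry and with ranks.

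The comparisons, the gene lists, the rule for named genes and most other settings were chosen before the data were examined. The rule took, per comparison, genes past the threshold with a mean of at least 1 CPM and no overlap between the conditions: the 6 largest rises and falls and the 4 of each with the smallest p. It also took 10 PD up and 10 PD down genes with the largest smaller change, up to 4 members of each list described, and 18 reference genes, 14 of which were tested.

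The alternatives were other scaling (median of ratios, upper quartile, library totals), other filters, DESeq2 1.42.0, limma-voom, unrounded values, the replicate number as a block, the 6 libraries compared alone, stricter thresholds and each library left out in turn. Leaving out ribosomal RNA genes or genes with counts that are not whole, list tests on library totals, list counts under each scaling, and tests of 337 gene families sharing a name were chosen after seeing the data. The method was tested on simulated data with 100 genes changed per fold: it found 83% and 86% of 2-fold changes in the comparisons of NaCl with KCl and with NGM, with 6 and 10 false calls. The simulated counts had the same spread for all genes and conditions, while the real NGM libraries differed more among themselves. These figures may therefore be too favourable, above all against NGM.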

Results

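Gene expression was measured by RNA sequencing in whole wild-type (N2) Caenorhabditis elegans that had spent 4 h on agar plates made with 1 of 3 salt solutions. About 2000 animals of the L4 stage, the last larval stage, made up each sample. The solutions were 100 mM NaCl, 100 mM KCl, and NGM solution, the salts of the standard growth medium, which holds 51 mM NaCl and 25 mM KPB. The bacteria the animals fed on had been treated with the same solution as the plate. Each condition had 3 biological replicates, 9 libraries in all. The submitters call the NaCl condition PD, an abbreviation their labels do not spell out, and define PD genes as those that differ in NaCl from both KCl and NGM.

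The NGM libraries held 8592683, 8855583 and 9473302 expected counts (replicates 1, 2 and 3), the KCl libraries 8738578, 10354296 and 10176934, and the NaCl libraries 11181235, 9192238 and 9473198. Between 15802 and 16217 genes had a count in each library, and ribosomal RNA genes took 3.31% to 5.09% of counts. Of 46904 genes listed, 13060 had enough counts to be tested. In a principal component analysis, the first component held 49.6% of the variance and separated the 3 NaCl libraries (42.57 to 44.37) from the other 6 (−23.51 to −17.07). The second component spread the NGM libraries, with NGM replicate 1 at 9.72, replicate 2 at −34.09 and replicate 3 at −17.13. On it the KCl libraries lay at 13.74 to 14.84 and the NaCl libraries at −3.87 to 2.06. NGM replicate 1 thus lay nearer to the KCl libraries than to the other NGM libraries. Cuticle collagens followed the NGM spread, with 112 of 119 tested genes higher in NGM replicate 1 than in replicate 2 (median log2 difference 0.78).

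The comparison of NaCl with KCl asks what changes with the cation at equal concentration. The largest rises were those of a pump gene and an exchanger gene. Transcripts of catp-2 (WBGene00015338, chromosome V 4934706 to 4939085), which encodes an alpha subunit of the Na+/K+ ATPase family, averaged 552 ± 15.7 CPM (SD, n = 3) in NaCl and had no count in any KCl or NGM library. Those of nhx-6 (WBGene00003734, chromosome II 1670829 to 1674401), a sodium/proton exchanger, averaged 425.2 ± 3.01 CPM (SD, n = 3) in NaCl and were likewise at 0 elsewhere. The annotation places 1 other gene across catp-2 on the opposite strand, and the strandedness of the libraries is not stated in the sources used here, so its reads are not told apart. Against a floor of 3 counts over the KCl group (0.106 CPM), catp-2 was at least 5196-fold higher and nhx-6 at least 4002-fold higher in NaCl. The related pump gene catp-3 (WBGene00015660, chromosome V 8076012 to 8079916) rose from 30.99 ± 0.308 CPM (SD, n = 3) in KCl to 721 ± 13.7 CPM (SD, n = 3), a log2 change of 4.54 with a standard error of 0.08 and an adjusted p of 1.24e-13 in edgeR's quasi-likelihood test. That standard error was derived as the log2 change divided by the square root of the test's F statistic.

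Levels are counts scaled to library size by edgeR (CPM), with the standard deviation over the 3 libraries of a condition, and positions are those of the Ensembl 115 annotation, as the build used by the authors is not given in the sources used here. Floors cover counting error only. Across the genome, 1590 genes rose and 1121 fell in NaCl against KCl at an adjusted p under 0.05, and 603 of the rises and 171 of the falls were at least 2-fold. With library totals in place of TMM factors, 1915 rose and 623 fell. Other genes past the threshold at 0 in all KCl and NGM libraries were C02E7.10, at 80.98 ± 2.69 CPM (SD, n = 3) in NaCl and at least 762-fold higher, F59A6.10, at least 45-fold higher, Y49F6B.12, at least 24-fold higher, nspe-6, at least 19-fold higher, and F14F9.3, at least 17-fold higher, each against KCl. F07C6.6 averaged 15.6 CPM in NaCl and 0.0397 CPM in KCl. Among genes with counts in every condition, srlf-34 rose by a log2 of 6.76, the cytochrome P450 gene cyp-14A5 by 3.90 and Y39B6A.1 by 2.65. The falls were smaller. Those of lon-1, a secreted regulator of body size, and of Y48E1B.8 were −3.17 and −3.48. The adjacent-numbered genes C10C5.5 and C10C5.3 changed by −4.08 and −2.70, irg-1, an infection response gene, by −3.52, T13F3.6 by −2.01 and acdh-2, an acyl-CoA dehydrogenase, by −1.67. F33H12.7 had 70 counts in KCl and 0 in NaCl. In each of these genes, all 3 NaCl libraries lay on 1 side of all 3 KCl libraries. The rule for naming genes by size or p required this, so it adds no support. The counts of C10C5.5 and C10C5.3 were not whole, so reads shared with similar genes enter them. When the model was fitted to the 6 libraries compared alone, 4207 genes passed.

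**Figure D1:**
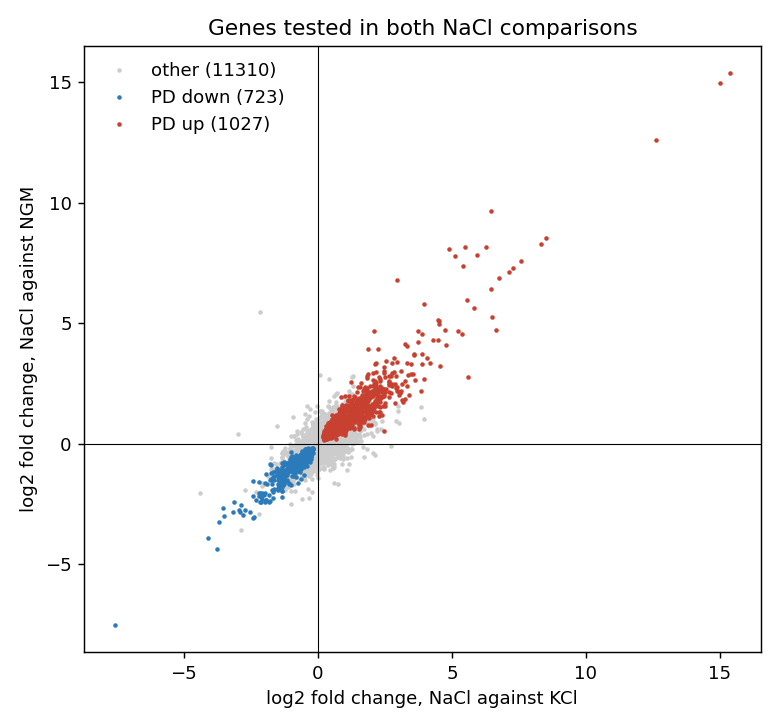
Each point is 1 of the genes tested, placed by its log2 fold change in NaCl against KCl on the horizontal axis and in NaCl against NGM on the vertical axis. The 1027 PD up genes lie at upper right and the 723 PD down genes at lower left, and the points past 12 on both axes are genes with no count in KCl or NGM, for which the fitted change is not a measured size.

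The list of pumps and cation transporters held 28 tested genes, of which 9 rose, 3 fell and 16 did not pass the test against KCl (14 and 4 passed up and down when adjusted over the list alone). Beside catp-2, nhx-6 and catp-3, the potassium/chloride cotransporter gene kcc-2 rose from 56.6 to 353 CPM, a log2 change of 2.64. The 3 that fell, named after their values were seen, were the sodium/calcium exchanger genes ncx-1 (−0.66), ncx-6 (−2.43) and ncx-7 (−0.79). The ubiquitous pump subunits moved little. The alpha subunit gene eat-6 differed by 0.24 (adjusted p = 0.0546) and the beta subunit gene nkb-1 by 0.02 (adjusted p = 0.866). As a set the list was higher in NaCl than other genes in the camera test (adjusted p = 7.17e-05, and adjusted p = 0.126 with an estimated correlation). The annotated span of kcc-2 overlaps many other annotated genes and the library strandedness is not stated in the sources used here, so its counts may include reads of neighbours. Without NGM replicate 1 eat-6 passed with an adjusted p of 0.000236, and without NGM replicate 2 with 0.0212.

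**Figure D2:**
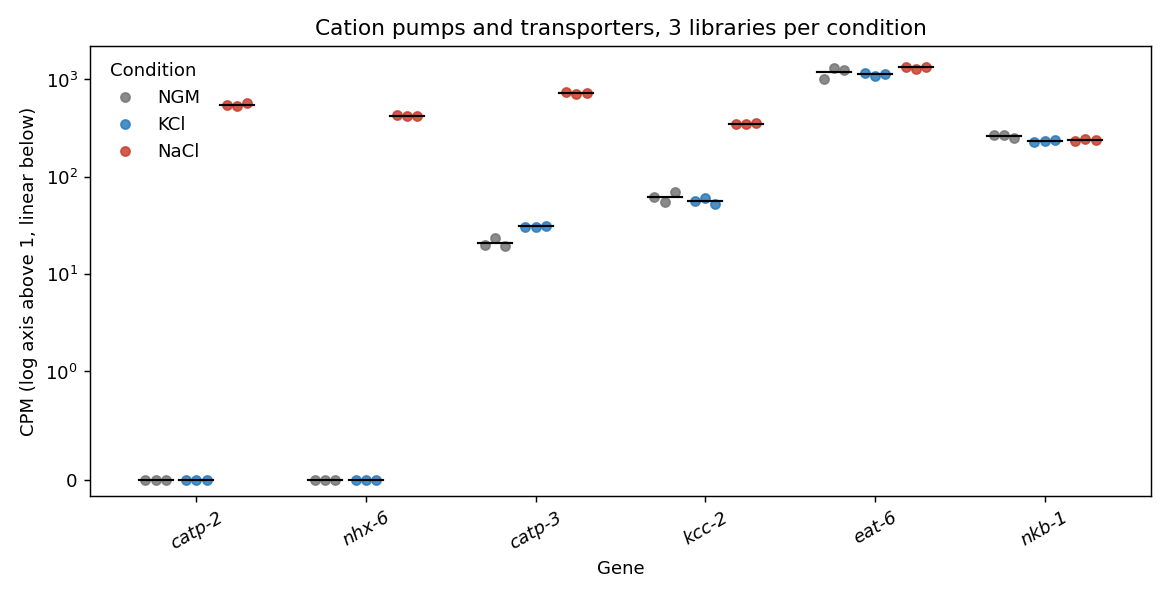
Levels in CPM of 6 pump and cotransporter genes, with 1 point per library, a bar at the mean of the 3 libraries of a condition, and a vertical axis that is logarithmic above 1 and linear below. The catp-2 and nhx-6 points of KCl and NGM all sit at 0, catp-3 stands at 721 CPM in NaCl against 30.99 in KCl, and eat-6 and nkb-1 lie close together in all conditions.

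Most cuticle collagens that passed the test rose in NaCl, while the yolk genes that passed fell. Of 119 tested cuticle collagens, 65 rose and 14 fell against KCl (69 and 18 when adjusted over the list alone), with a median log2 change of 0.91. The collagens col-97, col-14 and col-145 rose by 2.35, 2.67 and 1.59, while col-101 changed by −2.41. Of 6 collagens known from the adult cuticle, col-38, col-49, col-63 and col-138 rose by 1.72 to 1.93 and 2 did not pass (4 rose and 1 fell when adjusted over the list alone). The adult collagen col-19 differed by −0.35 (adjusted p = 0.22, and 0.00226 and 0.0233 without NGM replicates 1 and 2). Of 6 vitellogenins, the yolk proteins made in the intestine of adults, vit-1, vit-3, vit-4 and vit-5 fell, by −0.56 for vit-5 to −1.41 for vit-3, and vit-2 differed by 0.01 (0 rose and 4 fell when adjusted over the list alone). Camera gave adjusted p values of 1.28e-09 for the collagens, 0.00675 for the adult collagens and 4.16e-06 for the vitellogenins. With an estimated correlation these became an adjusted p of 0.423 for the collagens, 0.269 for the adult collagens and 0.192 for the vitellogenins. The counts of vit-1 to vit-5 were not whole, so the separate levels of these similar genes depend on how shared reads were assigned.

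The proteasome and endoplasmic reticulum stress lists were lower in NaCl by small amounts, while the autophagy and heat shock protein lists were not. Of 33 proteasome subunit genes, 22 fell and 0 rose against KCl (28 and 0 when adjusted over the list alone), with a median of −0.24. The core subunit gene pbs-7 changed by −0.39 and the regulatory subunit genes rpn-5 and rpt-4 by −0.34 and −0.29. Of 19 endoplasmic reticulum stress genes, 9 fell and 1 rose (10 and 2 when adjusted over the list alone), among them pdi-6, a disulfide isomerase (−0.74), hsp-3, a BiP chaperone (−0.51), and crt-1, calreticulin (−0.60). The second BiP gene, hsp-4, differed by −0.14 (adjusted p = 0.13, and 0.0299 without NGM replicate 1). Camera called both lists lower in NaCl, with an adjusted p of 6.89e-11 for the proteasome and 0.000104 for the endoplasmic reticulum list, and both calls held with an estimated correlation (adjusted p = 0.0132 and adjusted p = 0.0498). Of 26 autophagy genes, 7 rose and 0 fell (also 7 and 0 when adjusted over the list alone), with lgg-1 up by 0.59 and sqst-1 by 0.80. Camera called that list up (adjusted p = 0.0206, and adjusted p = 0.191 with an estimated correlation), a call lost without KCl replicate 2 (adjusted p = 0.0516). Of 18 heat shock protein genes, 3 rose and 3 fell (also 3 and 3 when adjusted over the list alone, camera adjusted p = 0.624). With library totals in place of TMM factors, 7 proteasome genes passed instead of 22 and their median was −0.18.

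Lists linked to defence gave mixed results, and the list of insulin pathway genes and DAF-16 targets was higher. That list mixes both kinds of gene, so its rise gives no direction of insulin signalling. Of 29 lysozyme and saposin genes, 13 rose and 1 fell (also 13 and 1 when adjusted over the list alone), with lys-7 up by 2.32, lys-2 by 1.56 and lys-4 by 1.53. Of 84 C-type lectins, 28 rose and 7 fell (30 and 10 when adjusted over the list alone), with clec-52 up by 2.75 and clec-218 by 2.02. Of 10 epidermal antimicrobial peptide genes, 5 rose and 0 fell (6 and 0 when adjusted over the list alone), with cnc-4 up by 5.56 and a median of 1.08. Camera gave that list an adjusted p of 0.00586, and an adjusted p of 0.451 with an estimated correlation. Of 20 intestinal infection genes, 13 rose and 6 fell (also 13 and 6 when adjusted over the list alone), with a median of 0.48, a mean of 0 and no call as a set (camera adjusted p = 0.127). Of these zip-2 rose by 0.91, while irg-1 and dod-17 changed by −3.52 and −1.65. Of 13 intracellular pathogen response genes, 2 rose and 0 fell (3 and 0 when adjusted over the list alone, camera adjusted p = 0.107, and 0.0453 without NaCl replicate 3). Of 17 genes of the insulin pathway and its DAF-16 targets, 6 rose and 0 fell (7 and 0 when adjusted over the list alone). The targets dod-3 and ctl-2, a catalase, rose by 6.26 and 1.80, and icl-1, of the glyoxylate cycle, from 252.5 ± 7.24 to 667.2 ± 11.4 CPM (SD, n = 3), while the transcription factor gene daf-16 itself differed by 0.19 (adjusted p = 0.0641), named after its value was seen, and the target sod-3 by 0.20 (adjusted p = 0.719). Camera gave an adjusted p of 4.52e-06 for the lysozymes, 0.0038 for the lectins and 7.17e-05 for the insulin list. With an estimated correlation the adjusted p was 0.104, 0.052 and 0.0498, so of these 3 the insulin list kept its call.

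**Figure D3:**
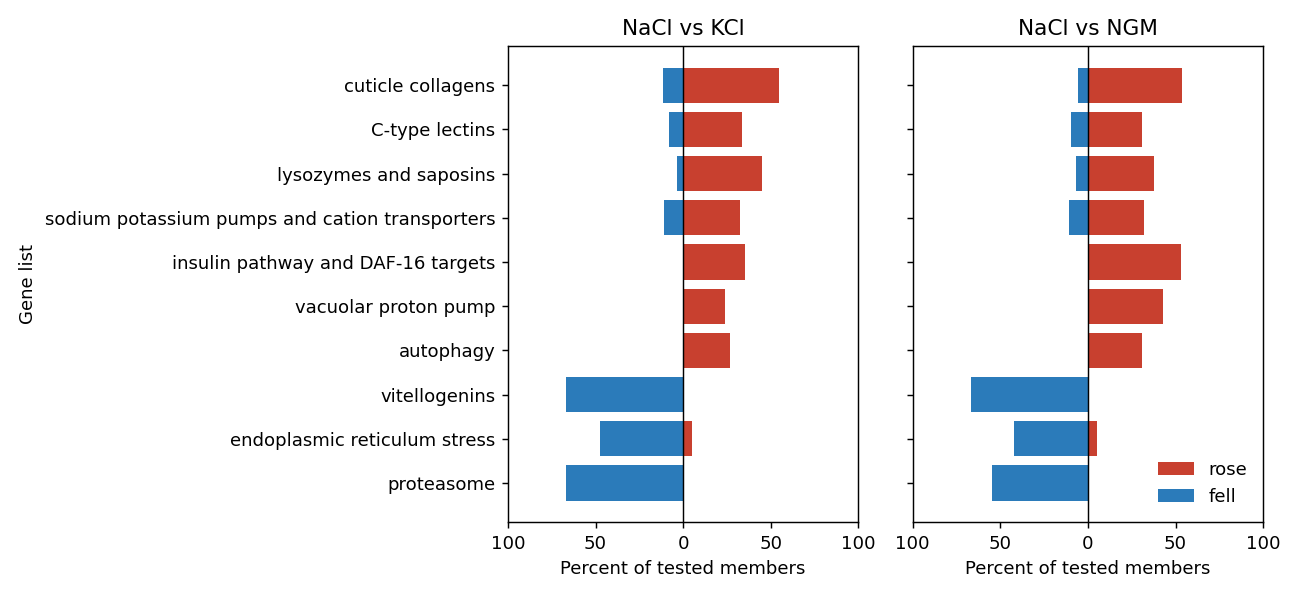
Percent of the tested members of 10 gene lists that rose (right of 0) or fell (left of 0) at an adjusted p under 0.05, in NaCl against KCl (left panel) and against NGM (right panel). Of the 33 proteasome genes 22 fell against KCl and 18 against NGM, and of the 119 cuticle collagens 65 and 64 rose.

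Tissue markers and other lists gave smaller or mixed changes against KCl. Of 13 pharynx markers, 7 rose and 0 fell (9 and 0 when adjusted over the list alone), with the muscle myosin myo-2 up by 0.33. Of 12 intestine markers, 6 rose and 2 fell (6 and 3 when adjusted over the list alone), with the protease gene cpr-1 up by 2.22 and the peptide transporter gene pept-1 at −0.45. Of 16 body muscle markers, 0 rose and 1 fell, and of 14 neuron markers, 3 rose and 0 fell. Of 85 sperm genes, 13 rose and 0 fell (median 0.23), and of 14 oocyte and eggshell genes, 0 rose and 6 fell (median −0.14). When adjusted over the list alone, 4 neuron markers and 11 sperm genes rose, and 1 muscle marker and 6 oocyte genes fell. With library totals in place of TMM factors, 2 oocyte genes fell (median −0.07) and 25 sperm genes rose. Camera called the pharynx, sperm and oocyte lists with adjusted p values of 0.000903, 0.000211 and 0.000506. With an estimated correlation these were an adjusted p of 0.0699, an adjusted p of 0.422 and an adjusted p of 0.25. The intestine, muscle and neuron lists had adjusted p values of 0.127, 0.352 and 0.624. In all, 22 of 44 tested lists passed, 15 up and 7 down, and 3 passed with an estimated correlation.

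Of 14 tested genes of the classical osmotic response, 7 rose and 1 fell against KCl (also 7 and 1 when adjusted over the list alone). Camera gave an adjusted p of 0.0057, and an adjusted p of 0.101 with an estimated correlation. The inositol transporter gene hmit-1.1 averaged 26.1 ± 2.68 CPM (SD, n = 3) in NaCl and 4.68 ± 0.847 CPM (SD, n = 3) in KCl, a log2 change of 2.48 (adjusted p = 1.44e-07). The glycerol synthesis gene gpdh-1 was at 22.9 ± 0.88 and 22.8 ± 2.7 CPM (SD, n = 3), a difference of 0.01 (adjusted p = 0.977), and it too is overlapped by 1 gene on the opposite strand. The trehalose synthesis gene tps-1 rose by 1.14 and lea-1, a stress protective protein, by 0.56. Among other reference stress genes, gst-4 differed by 0.03, sod-3 by 0.20 and hsp-6 by −0.16, none past the test (hsp-6 passed without NGM replicate 1 or 2, adjusted p 0.0362 to 0.0416). acs-2, of fatty acid oxidation, rose from 25.09 ± 1.41 to 71.02 ± 7.07 CPM (SD, n = 3; adjusted p = 3.42e-08). The peptide gene nlp-29 rose by 1.68 (adjusted p = 0.0201), a call lost without KCl replicate 1, 2 or 3 or NaCl replicate 2 (adjusted p 0.0668 to 0.0758). The call for hsp-70 (0.78, adjusted p = 0.0364) was lost without KCl replicate 2 or 3 or NaCl replicate 2 or 3 (adjusted p 0.109 to 0.14).

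The comparison of NaCl with NGM asks what 100 mM NaCl changes against the standard salts, which already hold sodium. Those hold 51 mM NaCl and 25 mM KPB, while the NaCl plates held 0 mM KPB. More NaCl and the lack of KPB thus cannot be told apart here. The largest rises were again those of catp-2 and nhx-6. In NaCl catp-2 was at least 5065-fold higher and nhx-6 at least 3901-fold higher than in NGM, with the floor at 0.109 CPM, and catp-3 rose from 21.1 ± 2.27 CPM (SD, n = 3), a log2 change of 5.09. The kcc-2 change was 2.49. Among other genes, C02E7.10 was at least 743-fold higher, and dod-3 and srlf-34 rose by 8.15 and 6.89. Whether the C02E7.10 counts are reads of the catp-2 locus, which was at 0 in the same libraries, was not tested. Among the largest falls were those of F54D8.10 (−3.08), D1022.3 (−3.05), C10C5.5 (−3.92) and mct-2 (WBGene00021227, −3.57), and the falls with the smallest p included C10C5.3 (−2.76), T13F3.6 (−2.13) and Y94H6A.10 (−2.11). acdh-2 went from 108.5 to 27.21 CPM. The invertebrate lysozyme gene ilys-3 averaged 10.5 CPM in NaCl and had no count in NGM.

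Against NGM, 1413 genes rose and 1201 fell, of which 525 and 202 changed at least 2-fold. Of the 119 cuticle collagens 64 rose and 7 fell (69 and 13 when adjusted over the list alone), and the median was 0.63. The vitellogenins vit-1, vit-3, vit-4 and vit-5 fell, with a median over all 6 of −0.63, and of 33 proteasome genes 18 fell and 0 rose (23 and 0 when adjusted over the list alone). Vacuolar proton pump genes rose in 9 of 21 cases and fell in 0 (10 and 0 when adjusted over the list alone), with vha-1 up by 0.37 and vha-6 by 0.26, and with library totals in place of TMM factors 5 rose. Of 17 insulin and DAF-16 genes 9 rose and 0 fell (also 9 and 0 when adjusted over the list alone). Of 20 intestinal infection genes 12 rose and 3 fell (16 and 3 when adjusted over the list alone), with the transcription factor gene zip-2 up by 1.13 and dod-17 at −1.18. Of 12 intestine markers 6 rose and 2 fell, of 13 pharynx markers 4 rose and 0 fell, and of 85 sperm genes 9 rose and 1 fell (6 and 2, 5 and 0, and 8 and 0 when adjusted over the list alone). Camera called these 3 lists up with adjusted p values of 0.0186, 0.00557 and 0.00356, and with an estimated correlation gave an adjusted p of 0.219, an adjusted p of 0.107 and an adjusted p of 0.554. The sperm call was lost without NGM replicate 2 (adjusted p = 0.0684). Of 14 oocyte and eggshell genes, 0 rose and 1 fell against NGM (also 0 and 1 when adjusted over the list alone). That list had no call as a set (camera adjusted p = 0.744), unlike against KCl. Of the list tests, 20 of 44 passed, 15 up and 5 down. With an estimated correlation, 6 kept their call, each named with its adjusted p: the proteasome (0.0289), the endoplasmic reticulum list (0.0413), the vacuolar pump (0.0413), the insulin list (0.0289), the C-type lectins (0.0289) and the intestinal infection genes (0.0331). The collagens and vitellogenins did not (adjusted p = 0.419 and adjusted p = 0.259). The mct-2 call (adjusted p = 0.0312) was lost without NGM replicate 2 or 3 or NaCl replicate 1 or 2 (adjusted p 0.0588 to 0.117).

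Of the 14 osmotic response genes, 6 rose and 3 fell against NGM (7 and 3 when adjusted over the list alone), with no call as a set (camera adjusted p = 0.159). The gpdh-1 level was lower in NaCl, at −1.09 (adjusted p = 0.000109), and so was that of gst-4, at −1.05 (adjusted p = 3.52e-05). hmit-1.1 rose by 0.54 (adjusted p = 0.0211), and that call was lost without NGM replicate 2 or 3 or NaCl replicate 1 or 2 (adjusted p 0.0519 to 0.0959). acs-2 rose by 1.08, fat-7, a fatty acid desaturase, by 0.33 (adjusted p = 0.0115, and 0.0587 without NaCl replicate 1), and hsp-70 by 0.88 (adjusted p = 0.0232, and 0.0755 to 0.0829 without NGM replicate 3 or NaCl replicate 2 or 3). nlp-29 differed by 0.98 (adjusted p = 0.144), and by 2.04 with an adjusted p of 1.84e-06 without NGM replicate 1. col-19 differed by −0.06 (adjusted p = 0.866) and by 0.29 without NGM replicate 1 (adjusted p = 0.0229). hsp-4, hsp-6, sod-3, vit-2, nkb-1 and eat-6 did not pass (eat-6 passed without NGM replicate 2, adjusted p = 0.0432), and hsp-16.2, pals-5, fmo-2 and mtl-1 had too few counts to test.

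The PD sets join both NaCl comparisons. The NaCl plates alone held neither KCl nor KPB, so the sets do not separate more NaCl from the lack of those salts. PD up held 1027 genes, 409 of them at least 2-fold higher in both, and PD down held 723, of which 124 were at least 2-fold lower in both. Beside the genes above, PD up included dod-3, at 190 ± 18.9 CPM (SD, n = 3) in NaCl against 2.43 in KCl and 0.688 in NGM, and srlf-34, at 144 ± 2.78 CPM (SD, n = 3) against 1.34 and 1.22. PD down included lon-1, at 4.57 ± 0.692 CPM (SD, n = 3) in NaCl against 41.4 in KCl and 32.9 in NGM, and Y47D7A.6, K12B6.11, C25F9.11 and the cytochrome P450 gene cyp-29A3, with log2 changes against KCl of −2.87, −2.93, −2.80 and −2.51. The changes were larger on the rising side, with a median smaller log2 change of 0.81 for PD up and a median size of 0.42 for PD down.

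Of the rises against KCl, 64.6% were in PD up, and 72.7% of the rises against NGM were. Independent calls would share 172 rises and 103.1 falls, but both comparisons use the same 3 NaCl libraries. In 20 simulations with no difference between conditions, that sharing gave at most 0 genes up and 1 down in both. Such low counts follow from the lack of any difference there. They do not show what sharing adds when many genes differ. The covariance between the log2 changes was 0.0286 in the simulations and 0.382 as observed, and their correlation 0.489 and 0.868. The 3 shared libraries are too few to be divided between the comparisons, so part of the excess may come from them. Only 7 genes passed both tests in opposite directions, with NaCl between the other conditions: aqp-8, fat-7, dod-24, ttr-14, dos-1, F17E9.4 and pgph-2, named after their values were seen. PD down counted 469 genes without NaCl replicate 2 and 472 without NaCl replicate 3.

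Between KCl and NGM, the conditions against which NaCl was set, 193 genes passed the test. That number depended on single libraries, with 1337 without NGM replicate 1, so it does not show the conditions to be alike. hmit-1.1 was lower in KCl, at 4.68 CPM against 18.02 ± 3.35 CPM (SD, n = 3) in NGM, a log2 change of −1.94 (adjusted p = 6.3e-05). So were gpdh-1 (22.78 against 49 ± 11.8 CPM (SD, n = 3), adjusted p = 0.00159), gst-4 (−1.08, adjusted p = 0.000551), the aquaporin gene aqp-8 (−1.08), cth-1, a cystathionine gamma-lyase (−0.99), and dos-1 (−2.25), which 3 genes overlap on the opposite strand. The desaturase gene fat-7 was higher in KCl, at 89.2 ± 4.75 CPM (SD, n = 3) against 35.7 ± 1.89 CPM (SD, n = 3), a log2 change of 1.32 (adjusted p = 1.93e-06), as were dod-22 (2.25), C32H11.4 (1.76), dod-24 (81.35 against 35.43 CPM) and the protease gene asp-14 (0.66). Of the pumps, catp-3 was higher in KCl by 0.55 (adjusted p = 0.00404).

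In all, 80 genes rose and 113 fell in KCl against NGM, 11 and 32 of them at least 2-fold. The osmotic list had 0 rises and 4 falls among 14 genes (2 and 6 when adjusted over the list alone, camera adjusted p = 0.0036, and adjusted p = 0.207 with an estimated correlation), with osm-7 and gpdh-2 at −0.62 and −0.37 beside hmit-1.1 and gpdh-1. Of 20 intestinal infection genes 4 rose and 0 fell (8 and 0 when adjusted over the list alone, adjusted p = 5.83e-06, and adjusted p = 0.0646 with an estimated correlation). Ribosomal protein genes were shifted slightly up as a set (median 0.15, adjusted p = 3.23e-10, and adjusted p = 0.5 with an estimated correlation), with 1 rise and 1 fall among 81. So was the oocyte and eggshell list (median 0.16, camera adjusted p = 8.07e-07, and adjusted p = 0.369 with an estimated correlation). Of its 14 genes, 0 rose and 0 fell (4 and 0 when adjusted over the list alone). No list of the 7 that passed kept its call with an estimated correlation. The osm-7 and gpdh-2 calls were lost without single libraries (adjusted p 0.0585 to 0.0823 for osm-7 without KCl replicate 1, 2 or 3 or NGM replicate 3, and 0.0531 to 0.152 for gpdh-2 without KCl replicate 1 or 3, any NaCl replicate or NGM replicate 3).

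These counts depended on single libraries more than those of NaCl. The comparison gave 1337 genes without NGM replicate 1, of which 867 rose and 470 fell. It gave 117 without NGM replicate 3, 72, 70 and 87 without KCl replicates 1, 2 and 3, and 121 without NaCl replicate 3. The cuticle collagens, with no call in all libraries (adjusted p = 0.623), were higher in KCl without NGM replicate 1 (adjusted p = 6.56e-06) and lower without NGM replicate 2 (adjusted p = 3.95e-06). With library totals in place of TMM factors, the median of all genes moved to −0.105 and 55 genes rose and 241 fell.

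**Figure D4:**
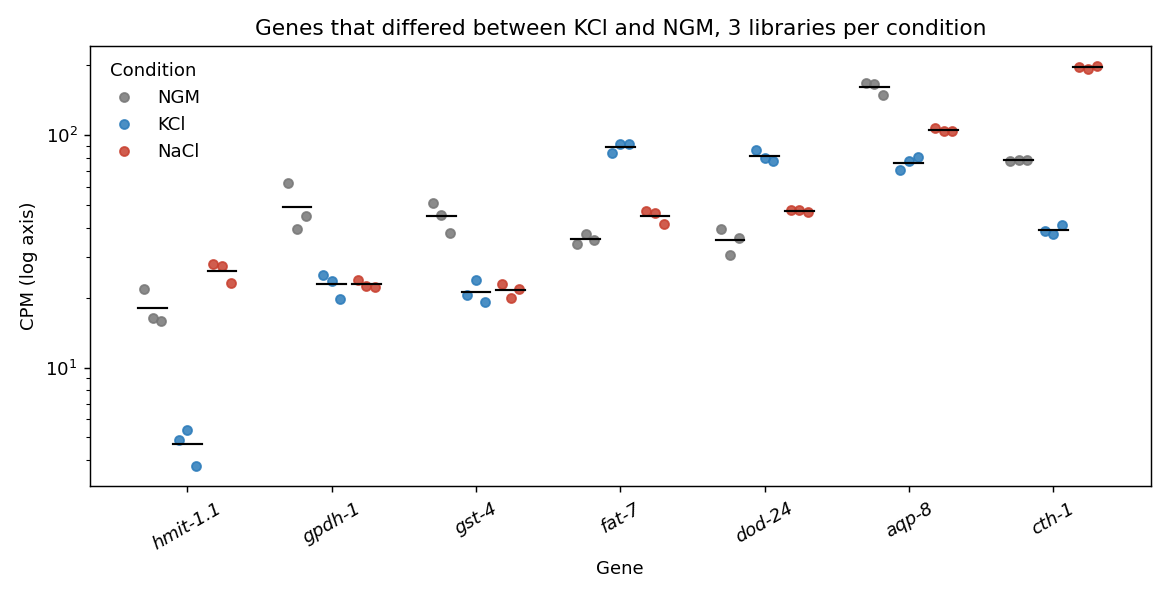
Levels in CPM of 7 genes that differed between KCl and NGM, with 1 point per library, a bar at the mean of the 3 libraries of a condition and a logarithmic vertical axis. hmit-1.1 and cth-1 are lowest in KCl and highest in NaCl, gpdh-1 and gst-4 are near equal in KCl and NaCl, and fat-7 and dod-24 are highest in KCl.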

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

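Leaving out ribosomal RNA genes or genes with counts that are not whole, running list tests on library totals, and counting list members under each scaling were chosen after the results were seen, and the other alternatives before. The NaCl counts stayed within 1.5 times of the reported ones in most settings. Settings within and beyond that range numbered 20 and 3 for NaCl against KCl, 21 and 2 for NaCl against NGM, and 20 and 2 against the mean. They numbered 21 and 2 for PD up, 19 and 4 for PD down, and 11 and 12 for KCl against NGM. At an adjusted p under 0.01 the counts were 1506, 1458, 71 (KCl against NGM), 1886 (against the mean), 645 (PD up) and 373 (PD down), and with an absolute log2 change of at least 1 they were 774, 727, 43, 752, 409 and 124. Both settings only remove genes. Fitted to the 6 libraries compared alone, NaCl against KCl gave 4207 genes, NaCl against NGM 2028 and KCl against NGM 73. The reported model estimates 1 spread per gene over all 9 libraries, though the NGM libraries differed more among themselves than the others. Its p values thus do not measure the spread of the compared groups alone. KCl against NGM gave 296 with library totals, 291 with no filter and 113 with the replicate block, and for these the cause was not tested. With the replicate block PD up held 924 genes and PD down 620, of which 914 and 615 were shared with the reported sets. Leaving out 1 library gave 1877 to 3771 genes for NaCl against KCl, 1803 to 3820 against NGM, 2165 to 4317 against the mean, 70 (without KCl replicate 2) to 1337 (without NGM replicate 1) for KCl against NGM, 767 to 1259 for PD up and 469 to 1049 for PD down. The replicate numbers showed no pairing of libraries (correlations of −0.141 to 0.038 over 9 pairs with the same number). With an estimated correlation 3, 6 and 0 lists passed in place of 22, 20 and 7, and with fry 4 passed for KCl against NGM. Leaving out 1 library gave 7 to 12 list calls for KCl against NGM. There the adjusted p of the cuticle collagens ran from 3.95e-06 (lower in KCl, without NGM replicate 2) to 0.752, and was 6.56e-06 in the other direction without NGM replicate 1. That of the sperm genes ran from 0.00507 (lower in KCl, without NGM replicate 2) to 0.559, and was 0.0289 in the other direction without NGM replicate 1. The log2 difference of col-19 in NaCl against NGM ran from −0.296 without NGM replicate 2 to 0.285 without NGM replicate 1. The cause was not tested. Of the calls for named genes when 1 library was left out, 4921 were the same, 381 no longer passed, 104 newly passed and 1 changed direction. Depth limits genes near the floor of 3 counts over a condition, for which no fold is given unless it is a lower bound.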

Other observations

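The tests of gene families here, the depth, paralog, age and library size tests, and the scaling of families were chosen after the results were seen, while the splits and regroupings, the test along the NGM spread and the test without the top genes were chosen before.

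Among 337 families of genes sharing a name, camera called several lower or higher in NaCl, none of those given here with an estimated correlation. All 8 genes of the CCT chaperonin (cct), which folds actin and tubulin, fell against KCl and 5 fell against NGM, with cct-3 at −0.41 and −0.36. Of 25 translation initiation factor genes (eif), 12 fell and 0 rose against KCl and 9 fell and 0 rose against NGM. Of 41 genes of the large mitochondrial ribosomal subunit (mrpl), 13 fell and 0 rose against KCl, and of 29 of the small subunit (mrps), 12 fell and 0 rose. Camera gave adjusted p values of 1.46e-05 (cct), 1.2e-06 (eif), 6.66e-07 (mrpl) and 1.57e-05 (mrps) against KCl. With an estimated correlation none passed (adjusted p = 0.207 for cct, eif and mrpl, and adjusted p = 0.27 for mrps). With library totals the falls against KCl numbered 4, 5, 8 and 5, and the medians kept their sign under every scaling tried.

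Among the called families with more rises than falls were grl, ttr and abu. Of 8 ground-like genes (grl), which are also in the list of hedgehog-related genes, 6 rose and 0 fell against both KCl and NGM, with grl-21 up by 3.01 and 2.19. Of 51 transthyretin-related genes (ttr), 19 rose, 2 fell and most did not pass against KCl and 20 rose and 2 fell against NGM. Of 11 abu genes, 8 rose and 0 fell against KCl and 5 rose and 0 fell against NGM. Camera gave adjusted p values of 1.46e-05 (grl), 8.4e-06 (ttr) and 7.52e-05 (abu) against KCl, and with an estimated correlation an adjusted p of 0.207 (grl), an adjusted p of 0.551 (ttr) and an adjusted p of 0.207 (abu). All these genes were named after their values were seen.

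Counts of catp-2 and nhx-6 were found in every NaCl library and in no KCl or NGM library. At the NaCl level, the KCl and NGM libraries would each hold at least 3700 counts of either gene, which argues against lower depth as the cause. Were catp-2 counts reads of its paralog catp-3, the catp-3 counts of KCl and NGM libraries would bring at least 128 catp-2 counts to each, and 0 were there. Reads of the gene across catp-2 on the other strand were not tested for. An effect of the salts, which the design names, may account for the pattern, whether of more NaCl or of no KCl and KPB. It stays a hypothesis, as the pattern was found and tested on the same data.

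More cuticle collagens rose than fell in NaCl, 65 and 14 of 119 against KCl, and 4 of 6 vitellogenins fell. Camera called both lists against KCl and NGM, but neither call held with an estimated correlation (adjusted p of 0.423 and 0.192 against KCl). If NaCl animals were uniformly older, vitellogenins should rise, but 4 of 6 fell against both other conditions and 0 rose. That fall is part of the pattern to be explained, so it is no separate test of age. Older age alone would not give it, but older age together with another cause was not tested. Uniformly younger animals stay open: 4 adult collagens rose against both, but col-7, named after its value was seen, fell against KCl when adjusted over the list alone, collagen levels go up and down within each moult, and lower vitellogenins go with younger animals. A shift along the difference between NGM replicates 1 and 2 may still contribute: the correlation across collagens was −0.02 (Spearman's rho), under the bound of 0.2 set beforehand as arguing against it, but that bound was wrong, because rho is blind to a shift common to all collagens and rests on 1 pair of libraries, while 112 of 119 collagens were higher in NGM replicate 1 (median 0.78) and 0 of 6 vitellogenins were (median −0.23). Over all 13060 tested genes rho was 0, which gives no sign of such a shift across genes as a whole. On the second principal component the NaCl libraries (−3.87 to 2.06) lay further toward NGM replicate 2 than the KCl libraries (13.74 to 14.84). A shift in that direction would lower collagens in NaCl against KCl, but neither value covers the collagens alone. For these genes younger animals, a shift along the NGM difference and an effect of the salt cannot be told apart. Whether age also bears on the sperm, oocyte, grl and abu genes was not tested.

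The NGM libraries differed more among themselves than those of KCl or NaCl, with a chi-square per gene of 26.38 between NGM replicates 1 and 2 against at most 3.94 within KCl or NaCl. A difference in library size is argued against, since these 2 totals had a ratio of 1.031 while KCl replicates 1 and 2, at a ratio of 1.185, had a chi-square of 2.61. A few genes do not account for it either, as the value without the 100 genes that add most was 12.73. No biological explanation was tested, since the labels give no group within NGM.

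For each comparison of 3 libraries with 3, only 10 splits exist, too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 2711 and 1 for NaCl against KCl, 2614 and 0 for NaCl against NGM, and 193 and 0 for KCl against NGM. Of 100 regroupings of the 9 libraries, 1, the real one, gave as many PD genes (1750, highest other 1536) and 1 as many genes against the mean (3211, highest other 2766). These shares lie under 0.05, which argues against chance. The 2 regroupings with the highest other counts kept the NaCl libraries as the group compared with the rest. The test thus bears on NaCl against the other libraries, not on how KCl and NGM were divided. The other 97 gave at most 5 PD genes, and at most 854 genes against the mean, in a regrouping that kept the NaCl libraries together as another group. Where the NaCl libraries were broken up, at most 19 genes differed from the mean.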
